A study of Mus musculus with 16 samples.

How the data were processed

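Gene expression was measured on 16 Illumina MouseWG-6 v2 bead arrays in C57BL/6J mouse embryos and yolk sacs at 9.5 days post coitum. Matings between heterozygotes for a deletion of exon 6 of rudhira, the gene whose symbol on the array is Bcas3, gave wild-type and homozygous mutant conceptuses, which were genotyped from the embryonic tail. Per the labels, total RNA was extracted with Trizol, checked on a Bioanalyzer, and turned into biotin-labelled cRNA with the Ambion MessageAmp kit. The 8 RNA samples fell into 4 groups of 2 (wild-type embryo, mutant embryo, wild-type yolk sac, mutant yolk sac), and each RNA sample was hybridized to 2 arrays. The repeat arrays are technical, so n is 2 per group throughout. Samples were grouped by their genotype and tissue labels. By the labels, the embryo and the yolk sac that carry the same number within a genotype came from 1 conceptus, which makes 4 conceptuses. Number 1 of a mutant and number 1 of a wild type share, by the labels, only the number.

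The deposited signal table holds the probe intensity on a linear scale, already background subtracted by the authors and not scaled between arrays. The software and its version are not given in the sources used here. Signals below 0 made up 28.1 to 32.7% of the values per array. The same table holds columns headed as p-values, which as deposited hold a score from 0 to 1, and how the authors made the deposited scores is not stated. Between 39.9 and 44.6% of the scores per array were at 0.95 or above and 2.03 to 3.36% at 0.05 or below. From that shape they were taken to be detection scores in which 1 goes with the brightest probes, an assumption that the sources do not settle. The score columns did not follow the signals beside them: the Spearman correlation of signal and score was 0.00157 to 0.0106 over the 16 arrays, while the score columns of any 2 arrays correlated at 0.824 or more. The scores were therefore matched to the signals by rank within each array. The matched scores set the signal above which a probe counts as detected and the background used in the normalization, so both rest on that assumption. The signal for detection was 10 to 28.8 over the arrays. A further 20 columns were unnamed and empty, and 0 columns of values were left unmatched to a sample.

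The processed values are log2 values that the authors scaled by 1 shift per array and centred on each probe's median within a tissue. Rebuilt in this way from the signals, with signals below 1 set to 1 and the shift estimated per array, 100% of them matched within 0.02. With the array's 75th percentile as the shift, 36.5% matched, with differences of up to 0.136, so what the shift was based on stays unknown. Every probe's median over the 8 arrays of a tissue was 0 within 0.006, so these values carry no level between tissues. Higher values stand for more signal. Their median per array ran from -0.28 to 0.15, at -0.28 to -0.15 in wild-type and 0.11 to 0.14 in mutant yolk sacs.

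Of the 45281 probes, 34885 carried 1 gene symbol, 18 several and 10378 none. The symbols of 34818 probes were found in the gene reference (GRCm38.p6, used for names only), 10 of them after an update of the symbol. A probe was kept when it was detected at a detection p under 0.05 on at least 4 of the 16 arrays, which left 21193 probes. For each gene the kept probe with the highest mean level was used, which gave 11332 tested genes of 19053 on the array. Several kept probes were present for 4574 of them.

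Signals were normalized with neqc (normal-exponential background correction with an offset of 16, quantile normalization and log2) in limma 3.58.1 under R 4.3.3, and the arrays of an RNA sample were averaged. Since no control probes were used, the background was taken from the detection p-values, which are 1 minus the matched scores. A linear model with 1 mean per group was fitted to the 8 samples (lmFit, eBayes), with 4 residual degrees of freedom and 3.35 prior degrees of freedom. It gave the genotype effect in yolk sac, the genotype effect in embryos, the difference between these effects (interaction), and the difference between the wild-type tissues. The series design states that the authors used 1 wild-type embryo (2) and 1 mutant embryo (1) with the 4 yolk sacs. That pair was fitted on these 6 samples, with 2 residual degrees of freedom that come from the yolk sacs alone, so embryos were assumed to vary as yolk sacs do. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. An exact permutation test of 2 against 2 samples cannot reach that threshold. The p-values measure the spread between these samples and no wider group of animals.

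The groups, the planned tests and settings, the gene lists and the rule for naming genes were fixed before the data were examined. Tests and settings added later are named as such where they are reported. The genes named were Bcas3, the 8 largest rises and the 8 largest falls past the threshold in each genotype comparison (both mutant samples on 1 side of both wild-type samples), up to 3 in each direction for the embryo pair, the 5 smallest p-values of the interaction, the 6 largest differences in each direction between tissues, and up to 4 members with the smallest p-values of each list described. Genes outside this rule were chosen after their values were seen and are said to be so, or come from a count within a list.

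The 24 lists of genes were endothelial, arteriovenous and Notch, hypoxia and glycolysis, primitive erythroid, blood progenitor and megakaryocyte, macrophage and leukocyte, visceral endoderm, extracellular matrix, matrix proteases and inhibitors, TGF-beta and BMP, cytoskeleton and migration, cardiac muscle, neural progenitor, neuronal differentiation, neural crest and head mesenchyme, somite and tailbud, Hox genes, cell cycle, p53 targets and cell death, integrated stress and unfolded protein response, sterol synthesis, immediate early and heat shock, trophoblast, and decidua and maternal. Each was tested with camera against all other genes at a preset correlation of 0.01, again with a correlation estimated per list, and with fry. Fry tests a list for a shift from 0 and does not compare it with other genes. A pass with fry is therefore no check of a shift beyond that of other genes. Between the wild-type tissues the p53 targets and cell death list passed with fry (adjusted p = 3.1e-04) and not with camera (adjusted p = 0.752). The estimated form was stricter for more than correlation. The endothelial list in yolk sac, at an estimated correlation of -0.0139, went from a camera p of 2.9e-06 to 0.00596. Between the wild-type tissues 0 lists passed with it. A call lost with it is therefore not by itself a sign that correlation between genes undid the call. The estimated correlation counted as well. In embryos the camera p of the visceral endoderm list, at a correlation of 0.673, went from 8.3e-04 to 0.468. That of the somite and tailbud list, at 0.00778, went from 0.00272 to 0.0381. Adjustment ran over the 24 lists of a comparison. A list needed 5 measured genes.

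Whether samples are paired was checked by correlating, across genes, each sample's deviation from its group. The correlation was 0.0421 for the wild-type and 0.220 for the mutant embryo and yolk sac of a conceptus, against 0.171 for yolk sacs and 0.192 for embryos that share only a number. The conceptus correlation estimated over all genes was 0.0482, so the conceptus was not part of the model and was tried as an alternative.

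The pipeline was tested on simulated data with 200 changed genes of 11332. A log2 change of 0.58 was recovered for 26% of changed genes in yolk sac and 7.5% in embryos, a change of 1 for 92.5% and 93%, and a change of 2 for 98.5% and 99.5%. Each value comes from 1 run, and the same spread per gene was used for both tissues. The gap at 0.58 is therefore no measure of a difference in sensitivity. False calls numbered 3 to 13 per run. The list test found 50 of 50 lists of 40 genes shifted by 0.3 and 0 of 50 unchanged ones, at an unadjusted p under 0.05. The simulated genes varied independently of each other. The real hypoxia and glycolysis, visceral endoderm and primitive erythroid lists had estimated correlations of 0.598, 0.673 and 0.730. False list calls from correlated genes were therefore not tested.

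The alternatives were quantile normalization without background correction, median scaling, an offset of 50, the authors' processed values, no detection filter, detection on all 16 arrays, the first or the repeat arrays alone, all 16 arrays with the RNA sample as a random block, all detected probes singly, eBayes with trend and robust options, only the tissue compared, blocks for the replicate number or the conceptus, the other pair of embryos, and each sample left out in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.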

Results

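RNA levels were measured in embryos and yolk sacs at 9.5 days post coitum. The mice were wild type or homozygous for the deletion in rudhira (Bcas3). The labels describe the mutants as growth retarded with abnormal vascularization. Each of the 4 groups held 2 RNA samples, each measured on 2 arrays. Between 17382 and 19576 of the 45281 probes were detected per array. The 75th percentile of the signal was 67 to 74.8 on the 4 mutant yolk sac arrays, 97.6 to 140.7 on the wild-type yolk sac arrays, 109.5 to 125.5 on the wild-type embryo arrays and 108.7 to 124 on the mutant embryo arrays. Repeat arrays of an RNA sample correlated at 0.996 to 0.998 across the 11332 tested genes. The SD of their difference was 0.142 to 0.202 on the log2 scale. The SD of the difference between the samples of a group was 0.34 in wild-type embryos, 0.23 in mutant embryos, 0.27 in wild-type yolk sacs and 0.29 in mutant yolk sacs. The first principal component held 91.6% of the variance, and the next components held 2.60% and 2.03%. On the first, embryos lay at -80.15 to -59.5 and yolk sacs at 63.4 to 70.5. On the second, wild-type samples lay at 9.15 to 12.1 and mutant samples at -17.6 to -4.73. The library labelled mutant embryo 2 lay at -17.6 there. The number of arrays and of samples limits the precision of every value.

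Bcas3, which encodes the cytoskeletal protein rudhira, was read by 2 probes, of which 1 was detected on all 16 arrays and the other on 0. The detected probe gave a mean signal of 1002 ± 343 (SD, n = 2) in wild-type yolk sacs and 256 ± 31.4 (SD, n = 2) in mutant yolk sacs. On the log2 scale the yolk sac difference was -1.27 with an SE of 0.33 and an adjusted p of 0.0991, so Bcas3 did not pass the threshold. The wild-type embryos gave signals of 331 and 391. Mutant embryo 1 gave 270, and the library labelled mutant embryo 2 gave 664, above both wild-type embryos. The embryo difference was 0.21 with an SE of 0.33 and an adjusted p of 0.880, and it was -0.37 (adjusted p = 0.925) without the library labelled mutant embryo 2 and -0.51 (adjusted p = 0.817) in the pair of embryos that the series design names. Whether the probe lies in the deleted part of the transcript is not known here. Every embryo direction below that uses all 4 embryos draws on the library labelled mutant embryo 2. Whether its Bcas3 signal speaks against its label cannot be told without the position of the probe. The yolk sac that shares its conceptus by the labels, mutant yolk sac 2, gave 278, against 759 and 1244 in the wild-type yolk sacs.

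**Figure D1:**
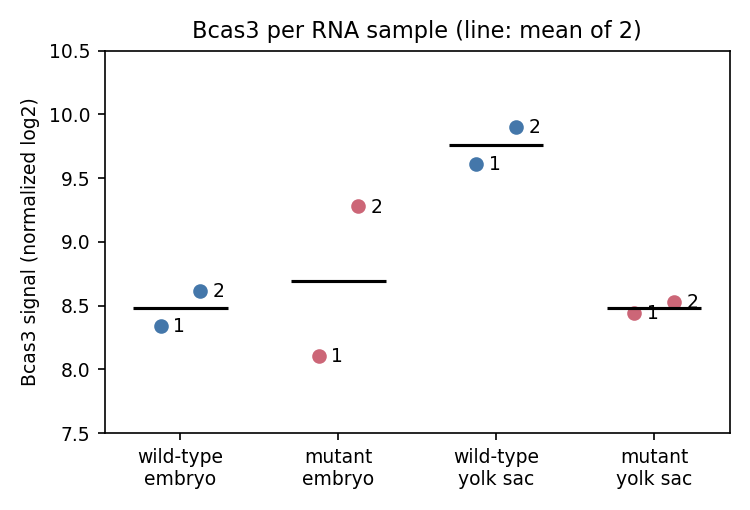
Bcas3 signal of the detected probe (normalized log2) for each of the 8 RNA samples, numbered within their group, with a line at the mean of 2. The mutant yolk sacs sit at 8.44 and 8.53 against 9.61 and 9.90 in the wild type, while the library labelled mutant embryo 2 sits at 9.28, above the wild-type embryos at 8.34 and 8.62.

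The yolk sac comparison asked which genes differ in the tissue where the first blood vessels form. Ptgis, which encodes prostacyclin synthase, rose 2.27-fold in mutant yolk sacs (log2 1.18, SE 0.12, n = 2 per group), and Hey1, a transcription factor downstream of Notch in arterial endothelium, rose 2.19-fold (log2 1.13, SE 0.16). Igf1, a growth factor, rose 2.15-fold (log2 1.10, SE 0.13). Nupr1, a stress-induced chromatin protein, fell by 1.30 on the log2 scale (SE 0.14), detected on 3 of the 4 mutant arrays, and Igfbp7, a secreted binding protein, fell by 1.21 (SE 0.13). The keratins Krt20 and Krt7, intermediate filament proteins of epithelia, fell by 1.35 (SE 0.19) and 1.20 (SE 0.15). The other largest rises were Cbln1 at 1.24, Dppa5a at 1.06, Plac1 at 1.03 and Retreg1 at 1.03. Tmem255a was detected on 0 of the 4 wild-type arrays and was at least 1.65-fold higher in mutants, while another of its probes gave a log2 change of 0.33. The other largest falls were Spink8 at -1.80, detected on 3 of the 4 mutant arrays, Sgk2 at -1.73, Slc7a3, a transporter of cationic amino acids, at -1.37, and Itih2 at -1.20. The adjusted p of these 16 genes ran from 0.0340 to 0.0443, and each had both mutant samples on 1 side of both wild-type samples. All 16 lost their call without wild-type yolk sac 1 (adjusted p = 0.0579 to 0.0801), wild-type yolk sac 2 (0.156 to 0.186) or mutant yolk sac 2 (0.104 to 0.137), and Plac1, Slc7a3, Krt20, Itih2 and Krt7 also without mutant yolk sac 1 (0.0612 to 0.0817).

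**Figure D2:**
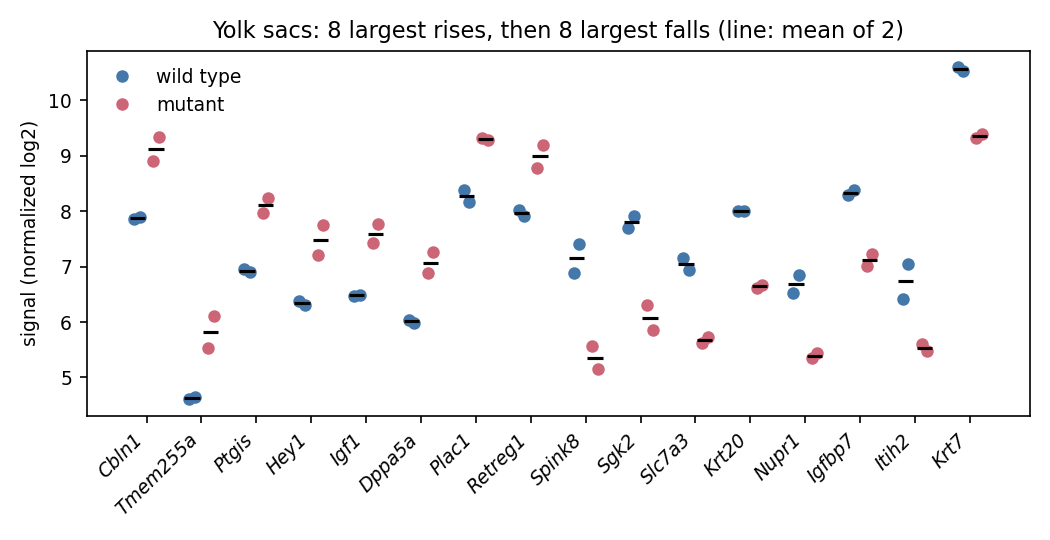
Normalized log2 signal of the 8 largest rises and the 8 largest falls past the threshold in yolk sac, with 1 point per RNA sample and a line at the mean of 2. Krt7 stands near 10.6 in the wild-type and 9.36 in the mutant yolk sacs.

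Endothelial genes were higher in mutant yolk sacs as a list. Of 31 measured members 3 rose, 0 fell and 28 did not pass, while 14 rose and 1 fell, Stab2 at -0.75, when adjusted over the list alone. Adgrl4, an adhesion receptor of endothelium, rose by 0.97 (SE 0.13), Sox7, a transcription factor of endothelial cells, by 0.96 (SE 0.14), and Pecam1, a junction protein of endothelium, by 0.53 (SE 0.09), with its adjusted p just under the threshold. Nos3, endothelial nitric oxide synthase, stood at 0.70 with an adjusted p of 0.0505. Adgrl4 (adjusted p = 0.0629 to 0.156) and Pecam1 (0.0729 to 0.185) did not pass with any single yolk sac left out, nor did Sox7 without wild-type yolk sac 1 (0.0724), wild-type yolk sac 2 (0.167) or mutant yolk sac 2 (0.106). The median change of the list was 0.34 (camera adjusted p = 7.1e-05), with 23 members above and 8 below 0, and the call was lost at an adjusted p = 0.143 with an estimated correlation. With fry the list passed (adjusted p = 0.0137). The mutant yolk sac arrays, the dimmest of the series, are those in which these genes were higher.

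Genes of the integrated stress and unfolded protein response were lower in mutant yolk sacs, with 3 of 28 measured members past the threshold, all of which fell, and 8 that fell when adjusted over the list alone. These were Nupr1, Atf4, a transcription factor of the amino acid response, at -0.86 (SE 0.11), and Asns, which encodes asparagine synthetase, at -0.61 (SE 0.11). The median was -0.13 (camera adjusted p = 0.00283). The list passed with fry (adjusted p = 0.0412), and its camera call was lost at an adjusted p = 0.466 with an estimated correlation. It was also lost with the authors' processed values, where the median was -0.04 and the adjusted p 0.0962, while the median of all genes was shifted by 0.10. With median scaling the list stood at -0.08 beside a shift of all genes of 0.09, so these values are no measure of a weaker change. The median was -0.22 without wild-type yolk sac 1 (adjusted p = 0.0433) or mutant yolk sac 2 (0.0479). Atf4 did not pass without wild-type yolk sac 1 (0.0628), wild-type yolk sac 2 (0.160) or mutant yolk sac 2 (0.106), nor Asns with any single yolk sac left out (0.0791 to 0.180).

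The other 22 lists did not pass in yolk sac, with adjusted p from 0.0769 to 0.943 and medians from -0.23 to 0.17. Single members passed within them. Tfrc, the transferrin receptor that erythroid cells use to take up iron, fell by 1.08 (SE 0.19), while the primitive erythroid list had a median of -0.23 and an adjusted p of 0.143. Ppbp, a platelet chemokine, was detected on 0 of the 4 mutant arrays and was at least 1.55-fold lower. The cytoskeletal regulator Cdc42 fell by 0.58 (SE 0.09), the heat shock protein gene Hspb1 fell by 1.04 (SE 0.17), and Hoxb6 rose by 0.82 (SE 0.11). Among matrix genes Col6a1 fell by 0.73 (SE 0.12) and the protease Mmp24 by 0.75 (SE 0.11), and Adam15 rose by 0.53 (SE 0.09). Plac1 belongs to the trophoblast list, whose median was 0.16 (adjusted p = 0.279). The visceral endoderm list stood at -0.13 (adjusted p = 0.279).

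In all, 144 of 11332 genes passed in yolk sac, 65 of which rose and 79 fell, and 2370 genes had an unadjusted p under 0.05 where chance gives 566.6. Without wild-type yolk sac 1 the count was 3, without wild-type yolk sac 2 it was 1 and without mutant yolk sac 2 it was 0, and none of these were among the 144. Without mutant yolk sac 1 the count was 110, of which 41 were among the 144. The split moved with scaling: median scaling gave 111 rises and 69 falls, and the authors' processed values 37 and 18, in which the median of all genes was shifted by 0.10. The count was 0 when the replicate number was a block and 0 when yolk sacs were fitted alone, with 2402 and 1673 genes at an unadjusted p under 0.05.

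In mutant embryos Stmn2, a microtubule regulator of neurons, fell by 1.92 on the log2 scale (SE 0.12, n = 2 per group), and Nefm, a neurofilament subunit, fell by 2.12 (SE 0.14). Dcx, a microtubule protein of migrating neurons, was detected on 0 of the 4 mutant arrays and was at least 3.21-fold lower. Hoxb9, which patterns the trunk, rose 3.62-fold (log2 1.85, SE 0.19). Hoxc9 rose by 3.57 (SE 0.37) and Cdx2, a regulator of posterior growth, by 2.64 (SE 0.44), each detected on 2 of the 4 wild-type arrays. The other falls were Sst at -2.51, detected on 2 of the 4 mutant arrays, Elavl3 at -2.15, Insm1 at -1.93, Barx1 at -1.93, and Inmt, which was detected on 0 mutant arrays and was at least 3.07-fold lower. The other rises were Lhx1 at 1.87, Etv2 at 1.77, Ret at 1.64, Prss35 at 1.58, detected on 2 wild-type arrays, and ccdc198 at 2.23, detected on 1 of them. The adjusted p of these 16 genes ran from 0.00161 to 0.0341. Ret, Sst, Nefm, Barx1, Stmn2, Inmt and Dcx passed with each embryo left out in turn. The calls of Hoxc9 (adjusted p = 0.0580) and Hoxb9 (0.0620) ended without the library labelled mutant embryo 2, those of ccdc198 (0.0740) and Prss35 (0.0914) without wild-type embryo 1, those of Cdx2 (0.0964 and 0.164) and Lhx1 (0.0557 and 0.0668) without either of these libraries, and those of Etv2 (0.0577 and 0.0548), Elavl3 (0.0504 and 0.0511) and Insm1 (0.0694 and 0.0577) without wild-type embryo 1 or 2.

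**Figure D3:**
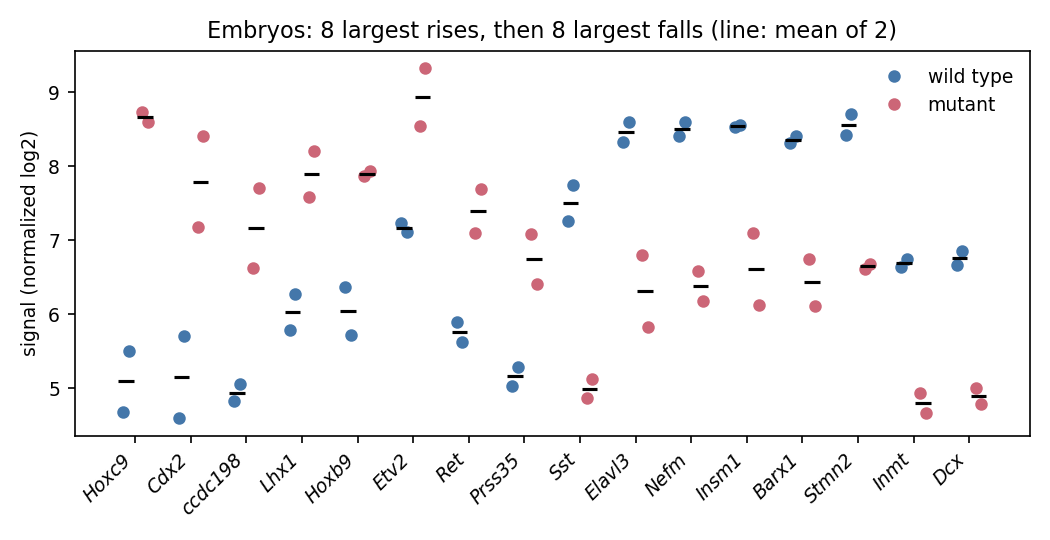
Normalized log2 signal of the 8 largest rises and the 8 largest falls past the threshold in embryos, with 1 point per RNA sample and a line at the mean of 2. Stmn2 stands at a mean of 8.56 in the wild-type and 6.65 in the mutant embryos.

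Of 26 measured genes of neuronal differentiation 17 fell, 2 rose and 7 did not pass, and 20 fell and 2 rose when adjusted over the list alone. Pou4f1, a transcription factor of sensory neurons, fell by 1.78 (SE 0.13), beside Stmn2, Nefm and Dcx. The members that rose were Lhx1, a transcription factor of interneurons that is also active in mesoderm and kidney precursors, and Ncam1, an adhesion molecule that is not restricted to neurons, at 0.51 (SE 0.09). The median was -0.94 (camera adjusted p = 2.4e-20), and the call was lost at an adjusted p = 0.136 with an estimated correlation. Of 28 genes of neural progenitors 7 fell, 0 rose and 21 did not pass, and 17 fell when adjusted over the list alone. Fabp7, a lipid-binding protein of radial glia, fell by 1.65 (SE 0.13), detected on 3 of the 4 mutant arrays, Dbx1 by 1.44 (SE 0.18), Fezf2, a forebrain transcription factor, by 1.09 (SE 0.15), and the Notch target Hes5 by 0.68 (SE 0.12). The median was -0.42 (adjusted p = 4.4e-13), again lost at an adjusted p = 0.136 with an estimated correlation. Dbx1 ended its call without wild-type embryo 1 (adjusted p = 0.0577), Fezf2 without each embryo but mutant embryo 1 (0.0507 to 0.113), and Hes5 without any single embryo (0.0996 to 0.289). Of 21 genes of neural crest and head mesenchyme 4 fell, 1 rose and 16 did not pass, and 8 fell and 1 rose when adjusted over the list alone. Barx1 fell by 1.93 (SE 0.19), Alx4 by 0.94 (SE 0.13) and Prrx1 by 0.81 (SE 0.13), all transcription factors of facial mesenchyme, and Foxc2 rose by 0.92 (SE 0.10). The median was -0.22 (adjusted p = 0.00228), lost at an adjusted p = 0.274 with an estimated correlation, and it was -0.13 without the library labelled mutant embryo 2 and -0.12 with the authors' processed values (adjusted p = 0.0112). Without the library labelled mutant embryo 2 Foxc2 (0.0600), Alx4 (0.0745) and Prrx1 (0.127) did not pass, nor did Alx4 and Prrx1 without wild-type embryo 1 (0.0706 and 0.136) or wild-type embryo 2 (0.0768 and 0.102).

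Of 22 Hox genes, which set position along the body axis, 8 rose, 1 fell and 13 did not pass, and 8 rose and 2 fell when adjusted over the list alone. Hoxa7 rose by 1.46 (SE 0.17), beside Hoxb9 and Hoxc9. Hoxd10 was detected on 0 of the 4 mutant arrays and was at least 2.76-fold lower. The median was 0.24 (camera adjusted p = 4.0e-04), and the call was lost at an adjusted p = 0.351 with an estimated correlation. Without wild-type embryo 2 the median was 0.14. Of 18 somite and tailbud genes 4 rose, 1 fell and 13 did not pass, and 8 rose and 2 fell when adjusted over the list alone. Tcf15 rose by 1.22 (SE 0.14) and Meox1 by 0.96 (SE 0.13), both transcription factors of somites, and Fgf17 fell by 0.70 (SE 0.10). The median was 0.12 (adjusted p = 0.00725), lost at an adjusted p = 0.274 with an estimated correlation and at 0.193 with the authors' processed values. It was 0.20 without the library labelled mutant embryo 2. Without the library labelled mutant embryo 2 Tcf15 (adjusted p = 0.0891), Meox1 (0.0668) and Fgf17 (0.156) did not pass. Meox1 did not pass without mutant embryo 1 (0.0680) or wild-type embryo 2 (0.0631) either, nor Fgf17 without wild-type embryo 1 (0.0749) or 2 (0.102).

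Genes of hypoxia and glycolysis were higher in mutant embryos as a list, with 1 of 28 members past the threshold, 0 that fell, and 4 that rose when adjusted over the list alone. P4ha2, a collagen prolyl hydroxylase, rose by 0.68 (SE 0.13), and did not pass with any single embryo left out, at an adjusted p of 0.0526 to 0.327. The median was 0.38 (adjusted p = 2.7e-07), lost at an adjusted p = 0.567 with an estimated correlation. The mean level of the list was 9.70 in the library labelled mutant embryo 2 and 8.99 to 9.15 in the other embryos, and without that library the median was 0.12, while without mutant embryo 1 it was 0.63. Primitive erythroid genes stood at a median of -0.58 (adjusted p = 9.4e-07, and 0.567 as an adjusted p with an estimated correlation), with 0 of 26 members past the threshold by either adjustment over all genes or adjusted over the list alone. Without the library labelled mutant embryo 2 that median was -0.15 (adjusted p = 0.0832), and without mutant embryo 1 it was -1.02. The embryonic globin gene Hbb-bh1 gave a signal of 14104 in that library and 24222 to 25576 in the other embryos. Blood progenitor and megakaryocyte genes had a median of -0.17 with 0 of 17 members past the threshold and 0 adjusted over the list alone (adjusted p = 0.0477, and an adjusted p = 0.567 with an estimated correlation). That call ended without wild-type embryo 1 (0.131), mutant embryo 1 (0.0711) or the library labelled mutant embryo 2 (0.0893), with the first arrays only (0.0857) and with an offset of 50 (median -0.08, adjusted p = 0.179). With the authors' processed values the median was -0.67 (adjusted p = 1.1e-06).

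Markers of other tissues differed between embryo libraries. Visceral endoderm genes, which the yolk sac expresses strongly, had a mean log2 level of 6.06 in wild-type embryo 1, 8.81 in wild-type embryo 2, 7.87 in mutant embryo 1 and 8.35 in the library labelled mutant embryo 2, against 11.5 to 11.8 in yolk sacs. Their median change was 0.46 with 0 of 34 members past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.00284, and an adjusted p = 0.802 with an estimated correlation). Without wild-type embryo 1 the median was -0.60 (adjusted p = 4.4e-12), and without the library labelled mutant embryo 2 it was 0.23 (adjusted p = 0.0832). It was 1.70 without wild-type embryo 2 and 0.30 with an offset of 50, and it stood at -0.95 in the pair of embryos that the series design names and at 2.13 in the other pair. The signal of Afp, a serum protein of visceral endoderm, was 49.6 in wild-type embryo 1 and 1101 in wild-type embryo 2. Trophoblast genes had a median of 0.51 with 0 of 9 members past the threshold and 1 that rose when adjusted over the list alone (adjusted p = 0.00404, and an adjusted p = 0.396 with an estimated correlation). That median was 0.30 without wild-type embryo 1 (adjusted p = 0.0412), 0.27 without mutant embryo 1 (0.0250), 0.33 with quantile normalization, 0.27 with an offset of 50 and 1.32 with the authors' processed values (0.0172). The decidua and maternal list had a median of 0.13 (adjusted p = 0.178). Among 14 lists that did not pass, with adjusted p from 0.115 to 0.996 and medians from -0.09 to 0.14, the endothelial list had 2 members that rose, Etv2 and Adgrl4 at 0.73 (SE 0.13, detected on 3 of the 4 wild-type arrays), and 1 that fell, Robo4 at -0.86 (SE 0.15). With fry, 5 of the 10 lists past the camera threshold passed. These were neuronal differentiation (adjusted p = 0.00229), neural progenitor (0.0122), neural crest and head mesenchyme (0.0341), somite and tailbud (0.0341) and Hox genes (0.0465). Hypoxia and glycolysis (0.398), primitive erythroid (0.422), blood progenitor and megakaryocyte (0.422), visceral endoderm (0.692) and trophoblast genes (0.315) did not pass with fry.

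In all, 241 of 11332 genes passed in embryos, 69 of which rose and 172 fell, and 1413 genes had an unadjusted p under 0.05. Without wild-type embryo 1 the count was 61, of which 41 were among the 241. Without wild-type embryo 2 it was 133 with 85 rises and 48 falls, 67 of them in common, and without the library labelled mutant embryo 2 it was 51, 50 of them in common. The authors' processed values gave 0 genes in limma, with 1059 at an unadjusted p under 0.05, and embryos fitted alone gave 24.

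The pair of embryos that the series design names, mutant embryo 1 and wild-type embryo 2, has no replicate embryo, and its spread comes from the yolk sacs. Sst, which encodes the neuropeptide somatostatin, was detected on 0 arrays of mutant embryo 1 and was at least 6.24-fold lower there. Kng1, which encodes a kininogen, was likewise undetected and at least 3.77-fold lower, and Apoa4, an apolipoprotein, fell by 2.21 (SE 0.20). The Apoa4 signal was 674 in wild-type embryo 2, 142 in mutant embryo 1 and 0.45 in wild-type embryo 1. Its direction therefore depends on the wild-type embryo compared. Hoxb9 rose by 2.15 (SE 0.17) and Hoxa7 by 1.85 (SE 0.16). In all 24 genes passed, 2 rises and 22 falls. Of the falls 11 were among the 1805 genes, 15.9% of those tested, that passed between the wild-type tissues at more than 2-fold higher in yolk sac. That set also held 18 of the 69 rises and 2 of the 172 falls found with all 4 embryos. Of the pair's genes 13 of the 24 also passed in the same direction with all 4 embryos. The other pair of embryos gave 208 genes, with 121 rises and 87 falls. Of the 24 genes 22 passed there too, 13 in the same direction and 9 in the opposite one. The log2 changes of the pairs correlated at 0.224 across 11332 genes, which are not independent replicates. The count was 0 with the authors' processed values, where the median of all genes was shifted by 0.10 (608 genes at an unadjusted p under 0.05), and 9 with an offset of 50, with 2 rises and 7 falls.

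The interaction asked whether the genotype effect differed between embryo and yolk sac. It was lower in embryos for Stmn2, by -2.41 (SE 0.17), for Nefm, by -2.40 (SE 0.20), for the methyltransferase gene Inmt, by -2.19 (SE 0.16), for Crym, which encodes a thyroid hormone binding protein, by -1.77 (SE 0.14), and for Myt1, a transcription factor of neural cells, by -1.58 (SE 0.14). The adjusted p of these genes ran from 0.0104 to 0.0124. Inmt and Myt1 were detected on 0 mutant embryo arrays, so their values rest on levels at background. In yolk sac Crym and Myt1 were detected on 0 of the 8 arrays and Stmn2, Nefm and Inmt on some of them. In all 38 genes passed, 8 higher and 30 lower in embryos, of which 32 also passed in embryos and 8 in yolk sac. Of the 30 lower ones 20 were detected on 0 of the 8 yolk sac arrays and 4 on all 8. A fall in yolk sac could not have been measured for the 20, so for these the difference restates the embryo effect. With only genes detected on all 16 arrays tested, 0 passed (1604 at an unadjusted p under 0.05). Of the neuronal differentiation list 10 members were lower and 1 was higher, against 21 and 3 adjusted over the list alone, with a median of -1.03 (camera adjusted p = 1.7e-13, and an adjusted p = 0.155 with an estimated correlation). Of its 26 members 13 were detected on 0 yolk sac arrays, and the 5 detected on all 8 had a median of 0.82, so the list is no test of a difference between tissues. The endothelial list had a median of -0.25 with 0 of 31 members past the threshold and 8 lower when adjusted over the list alone (adjusted p = 5.0e-04, and an adjusted p = 0.155 with an estimated correlation). Without wild-type yolk sac 1, wild-type yolk sac 2, mutant yolk sac 2 or the library labelled mutant embryo 2 the count was 0 in each case, with 2444, 1769, 2173 and 1416 genes at an unadjusted p under 0.05. It was 11 without wild-type embryo 1 (1 higher and 10 lower) and 86 without mutant embryo 1 (15 and 71). Without wild-type embryo 2 it was 72, and the split turned to 54 higher and 18 lower. Quantile normalization gave 28 higher and 54 lower, an offset of 50 gave 51 and 92, and the authors' processed values 0 and 2. With the conceptus as a fixed block 0 genes passed (1982 at an unadjusted p under 0.05), and 73 with the conceptus as a random block.

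Few genes passed the genotype comparison in both tissues. Adgrl4 and P3h2 rose in both, where 0.396 genes would be shared by chance (Fisher's exact p = 0.0595, two-sided), 0 fell in both where chance gives 1.20 (Fisher's exact p = 0.635), and Ncam1 and Isl1, which was detected on 0 of the 4 wild-type yolk sac arrays, went opposite ways. P3h2 was named after its values were seen. Across 11332 genes the effects correlated at a Pearson r of 0.0898 and a Spearman rho of 0.00150. The chance counts and the correlations take every gene as measurable in both tissues. Of 26 neuronal differentiation genes 13, and of 28 neural progenitor genes 19, were detected on 0 yolk sac arrays. The small overlap is therefore no measure of a difference between the tissues.

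The wild-type tissues differed in 7874 genes, 3767 higher in yolk sac and 4107 higher in embryo. Spp2 at a log2 difference of 6.10 (SE 1.39), Apoa4 at 6.04, Pdzk1 at 6.03, Apob, which encodes the main protein of secreted lipoproteins, at 6.00, Amn, which encodes a part of the cubilin receptor of visceral endoderm, at 5.87 and 4933402E13Rik at 5.83 were the genes most above embryo, each detected on 2 of the 4 wild-type embryo arrays. In wild-type embryo 1 they were not detected, so only their difference from that embryo is a lower bound. The differences ran from 3.22 to 3.85 against wild-type embryo 2 alone and from 7.815 to 8.764 against wild-type embryo 1 alone. The 6 genes most above yolk sac were Crabp1 and genes of heart and muscle contraction. Myl2 was at least 156-fold, Myl7 at least 76.7-fold and Myl1 at least 59.2-fold higher in embryo, all detected on 0 of the wild-type yolk sac arrays. Crabp1, a retinoic acid binding protein, was at least 87.6-fold higher, and Myl4 and Actc1 stood at -7.19 (SE 0.10) and -6.96 (SE 0.52), Actc1 detected on 2 yolk sac arrays. Of 34 visceral endoderm genes 33 were higher in yolk sac, with a median of 4.86 (camera adjusted p = 1.1e-07, and an adjusted p = 0.397 with an estimated correlation). Of 26 primitive erythroid genes 18 were higher, with a median of 1.31 (adjusted p = 0.00103, and an adjusted p = 0.528 with an estimated correlation). The neural progenitor median was -2.68, with 27 of 28 genes lower in yolk sac, the neural crest and head mesenchyme median -3.16, with 20 of 21, and the cardiac muscle median -2.96, with 23 of 27 lower and 1 higher. These 3 calls were lost at an adjusted p = 0.113, 0.113 and 0.158 with an estimated correlation. The counts of all 5 lists were the same when adjusted over the list alone. Lists for macrophages (0.87), extracellular matrix (0.81), the stress response (0.52) and trophoblast (1.74) were also higher in yolk sac, and those for neuronal differentiation (-2.40), somite and tailbud (-2.33), Hox genes (-1.71), arteriovenous and Notch genes (-1.12) and the cell cycle (-0.67) lower. None of the 14 lists passed with an estimated correlation, where the lowest was an adjusted p = 0.113 with an estimated correlation, and the arteriovenous and Notch call also ended without wild-type yolk sac 2 (adjusted p = 0.0556). The visceral endoderm median was 3.15 without wild-type embryo 1. With fry 21 of the 24 lists passed between the tissues.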

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

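Among the tests below, leaving out single embryo libraries for the neuronal list and comparing endothelial with erythroid genes were chosen only after the result was seen.

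The results singled out here are genotype effects that differed between embryo and yolk sac by the interaction test, which 38 genes passed. Among the genes named in the results, the embryo effect lay below the yolk sac effect on the log2 scale for Sst by -2.62, Stmn2 by -2.41, Nefm by -2.40, Inmt by -2.19, Hoxd10 by -1.98, Barx1 by -1.90, Crym by -1.77, Pou4f1 by -1.77, Dcx by -1.70, Fabp7 by -1.59, Myt1 by -1.58, Igf1 by -1.51 and Isl1 by -1.45. It lay above the yolk sac effect for 8 of the 38, among them Ncam1, by 1.05. Without wild-type embryo 2 the interaction count was 72, with 54 higher and 18 lower in embryos. Inmt, Dcx, Hoxd10 and Myt1 were not detected on any mutant embryo array, and their values rest on levels at background. In yolk sac Sst, Barx1, Crym, Pou4f1, Dcx, Fabp7 and Myt1 were detected on 0 of the 8 arrays, Stmn2, Nefm, Inmt, Hoxd10 and Isl1 on some, and Igf1 and Ncam1 on all 8. Over all interaction genes lower in embryos this was 20 on none and 4 on all 8 of 30. For genes not detected in yolk sac a fall there could not have been measured, so the difference restates the embryo effect. With only genes detected on all 16 arrays tested, 0 passed (1604 at an unadjusted p under 0.05). With the library labelled mutant embryo 2 left out, 0 genes passed the interaction (1416 at an unadjusted p under 0.05), and the count was also 0 without wild-type yolk sac 1, wild-type yolk sac 2 or mutant yolk sac 2. With the conceptus as a fixed block 0 genes passed (1982 at an unadjusted p under 0.05), and 73 with the conceptus as a random block. The genotype effect was lower in embryos than in yolk sac for the lists neuronal differentiation (median difference -1.03), neural progenitor (-0.42), neural crest and head mesenchyme (-0.32) and endothelial (-0.25). It was higher for visceral endoderm (0.64), hypoxia and glycolysis (0.29) and the integrated stress and unfolded protein response (0.28). None of these 7 lists passed with an estimated correlation, where the lowest adjusted p was 0.155. With fry hypoxia and glycolysis (adjusted p = 0.666) and visceral endoderm (0.788) did not pass, and the others did. Members detected on 0 yolk sac arrays numbered 13 of 26 for neuronal differentiation, 19 of 28 for neural progenitor and 13 of 21 for neural crest and head mesenchyme, so these 3 lists are no test of a difference between tissues. Their members detected on all 8 arrays had medians of 0.82 over 5 genes, -0.37 over 5 and -0.50 over 6. The visceral endoderm difference was -0.57 without wild-type embryo 1 and 2.21 without wild-type embryo 2. With the authors' processed values and with median scaling the neural crest difference was -0.58 and -0.59 and the neural progenitor difference -0.70 and -0.73. The stress response difference was 0.16 without wild-type yolk sac 1 and 0.17 without mutant embryo 1. The hypoxia and glycolysis difference did not pass without the library labelled mutant embryo 2 (0.05, adjusted p = 0.416) or mutant yolk sac 1 (0.10, adjusted p = 0.191), and it was 0.53 without mutant embryo 1 and 0.49 without mutant yolk sac 2.

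Neuronal differentiation genes were lower in mutant embryos, a list call that was lost at an adjusted p = 0.136 with an estimated correlation. The list passed with fry (adjusted p = 0.00229), which does not compare it with other genes. Yolk sac tissue diluting the embryo RNA would shift all embryo genes by 0.00436 on the log2 scale between genotypes, and by -0.04 if the wild-type embryos had held none, while the quartiles of the list's changes were -1.30 and -0.53, which argues against dilution as the source. A single deviating library is argued against as well, since the list's median stayed between -1.08 and -0.84 with each embryo left out in turn. The genotype, and the growth retardation that the labels give for the mutants, remain open and were not tested against each other, because every mutant carries both. The pair of wild-type embryo 2 and mutant embryo 1, which leaves out the library labelled mutant embryo 2, gave a median of -0.82.

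Endothelial genes were higher in mutant yolk sacs, on the dimmest arrays of the series. That list call was lost at an adjusted p = 0.143 with an estimated correlation. The list passed with fry (adjusted p = 0.0137), which does not compare it with other genes. The list's median of 0.34 lay at percentile 100 of 10000 random lists of genes of like signal level, whose highest median was 0.201, which argues against a shift tied to signal level. A lower share of visceral endoderm would raise the other cell types alike. The endothelial list changed by a mean of 0.261 and the primitive erythroid list by -0.254, a difference of 0.515 (permutation p = 1e-05, the smallest that 100000 resamples can give). A separate fall of erythroid genes would give such a difference as well, so a lower share of visceral endoderm is not excluded. That permutation runs across genes, which are not independent replicates. A change in the share of endothelium, a change of expression within it, the genotype and the growth retardation remain open and untested.

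Visceral endoderm genes differed between embryo libraries that share a genotype. The marker list, fixed beforehand, had mean log2 levels of 6.06 and 8.81 in the wild-type embryos and 7.87 and 8.35 in the mutant embryos. For the test 101 genes were chosen for a level more than 5 log2 units higher in wild-type yolk sac than in wild-type embryo 1, so the share in that embryo is set by the choice. In the other embryos the median share of the yolk sac signal was 6.29% in wild-type embryo 2, 2.39% in mutant embryo 1 and 3.72% in the library labelled mutant embryo 2. In these 3 libraries the upper quartile of the share was 1.41 to 1.81 times the lower one. The genes between the quartiles thus sat at a like share, which yolk sac tissue carried into the embryo samples would give. Genes outside the quartiles differed more. In mutant embryo 1 the signal of Ttr was 3400, against 22820 and 26331 in wild-type yolk sacs. That of Apoa4 was 142, against 8557 and 10199. A single share for all of the chosen genes is therefore not shown. The marker list contributed 23 of the 101 genes. Afp gave a signal of 1101 in wild-type embryo 2 against 8857 and 12356 in wild-type yolk sacs. Gut or liver precursors of the embryo, which express some of these genes, remain open and untested as a further source.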

How the results depend on the processing

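The settings added after seeing the data were the fits without genes higher in yolk sac, the authors' processed values with centred arrays, and the 3 other normalizations for the lists. Among the counts of genes, 34 stayed within 1.5 times of the value reported and 54 did not. For yolk sac (144 genes) the count was 55 with the authors' processed values (22 of them in common), 81 with these values centred per array, 241 with an offset of 50, 348 with the trend and robust options, 873 with 16 arrays and the RNA sample as a random block, 23 with probes taken singly, and 0 with the first arrays only, with only the tissue compared and with the replicate number as a block (1820, 1673 and 2402 genes at an unadjusted p under 0.05). The labels give these samples no more than a shared number, so that block is not part of the reported fit. Their deviations correlated at 0.171 in yolk sac and 0.192 in embryos, against 0.0421 and 0.220 within wild-type and mutant conceptuses. A factor tied to the number is therefore not excluded. For embryos (241) it was 0 with the authors' processed values, 4 with genes detected on all 16 arrays, 128 with the repeat arrays, 588 with 16 arrays and 24 with embryos alone, and 174 with the replicate number as a block. For the stated pair (24) it was 48 with quantile normalization, 51 with median scaling, 9 with an offset of 50, 100 with trend and robust options, 289 with 16 arrays, 208 for the other pair, 7 without the 1805 genes higher in yolk sac (by more than 2-fold past the threshold, or 32-fold against wild-type embryo 1), and 0 with the authors' processed values, no detection filter, detection on all 16 arrays, the first arrays, the repeat arrays or probes taken singly (608, 1109, 320, 719, 560 and 929 at an unadjusted p under 0.05). For the interaction (38) it was 82 with quantile normalization, 212 with median scaling, 143 with an offset of 50, 2 with the authors' processed values, 81 without a detection filter, 0 with detection on all 16 arrays (1604 at an unadjusted p under 0.05), 18 and 15 with the first and the repeat arrays, 656 with 16 arrays, 23 with probes taken singly, 116 with trend and robust options, 73 with the conceptus as a random block and 0 with the conceptus as a fixed block (1982 at an unadjusted p under 0.05). The tissue count (7874) was 13744 with probes taken singly, where more features were tested, 7716 with the conceptus as a fixed block, and has no value from the authors' processed values, which are centred per tissue. Samples left out in turn gave 0 to 110 genes in yolk sac, 51 to 207 in embryos, 0 to 86 for the interaction and 6555 to 7337 between tissues; where this left 1 sample in a group, it was assumed to vary like the other groups. Fits on 1 tissue have fewer samples, and treating 16 arrays as the units adds technical repeats; for the other shifts the cause was not tested. Bcas3 with 1 embryo left out ran from -0.37 without the library labelled mutant embryo 2 to 0.80 without mutant embryo 1, and in the stated pair from -0.54 to -0.40 over the settings. With 1 embryo left out the visceral endoderm list ran from -0.60 without wild-type embryo 1 to 1.70 without wild-type embryo 2 in embryos (-0.95 in the stated pair and 2.13 in the other), and from -0.57 to 2.21 without the same embryos for the interaction. For named genes, 1726 of the alternatives kept direction and side of the threshold, 388 lost the threshold, 70 gained it and 1 reversed. For lists these were 356, 52, 0 and 2, and with an estimated correlation 33 of 33 list calls were lost. That includes the 14 calls between the wild-type tissues, so the loss of the threshold alone does not tell list calls apart. The camera p with an estimated correlation did differ. In embryos it was 0.00626 for neuronal differentiation and 0.468 for visceral endoderm. Of the 33 called lists 26 also passed with fry and 7 did not. Signal over background limits genes such as Dcx and Inmt, whose mutant levels lie at background.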

Other observations

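The test of Hox genes by position below was chosen only after the result was seen.

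Some changes fell outside the gene groups that moved together. In mutant embryos Vtn, which encodes the matrix protein vitronectin, fell by 1.25 (SE 0.18), Trib3, a pseudokinase of the stress response, fell by 1.32 (SE 0.24), and Gadd45g fell by 0.79 (SE 0.15), while Egr2, a transcription factor of the hindbrain, rose by 1.23 (SE 0.18) and was detected on 2 of the 4 wild-type arrays. The lists these genes belong to did not pass in embryos. In yolk sac the neuronal list did not pass either, yet Gap43 rose by 0.86 (SE 0.15), and Isl1, detected on 0 of the 4 wild-type and 3 of the 4 mutant arrays, was at least 1.09-fold higher. Cntn2 fell by 0.82 (SE 0.10), while another of its probes gave -0.13, and Ncam1 fell by 0.54 (SE 0.09).

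The conceptuses were genotyped from the embryonic tail, and how much tail tissue each embryo sample held is not known here. If posterior axial tissue made up more of the mutant embryos, the change of Hox genes would rise with their paralog number. A rise of that kind was not established. The Spearman correlation of paralog number and embryo log2 change was 0.271 across 22 Hox genes (permutation p = 0.22, two-sided), and the Pearson correlation was 0.232. Paralogs 1 to 4 had a median change of 0.16 over 9 genes, paralogs 5 to 8 a median of 0.65 over 7, and paralogs 9 and 10 a median of 0.43 over 6, of which 3 rose and Hoxd10 fell. The genes are too few to tell a trend with position from none, genes are not independent replicates, and direction in these embryos draws on the library labelled mutant embryo 2.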
